A study of Mus musculus with 8 samples.

How the data were processed

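Anti-Brdt ChIP-seq was carried out on spermatocytes and round spermatids of adult wild-type mice and of mice with a deletion of the first bromodomain of Brdt. Per the labels' protocols, testis cell suspensions were fractionated on a BSA gradient and the fractions of each cell type were pooled. For wild type, the labels' protocols give C57BL/6 mice, a pool of 10 mice per fractionation, digestion with MNase to fragments of about 200 bp, and 500 µg of chromatin with 0.6 µg of antibody per ChIP; the strain, pool size and chromatin preparation of the BD1del samples were not given in the sources used here. All libraries were bar-coded paired-end libraries with an insert of about 150 bp, per the labels' protocols. Of the 8 samples, 4 were ChIP and 4 were input libraries, and each of the 8 groups of stage, genotype and antibody had 1 library. The inputs had no list of their own here and entered only as the control counts of each ChIP list.

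The deposited lists were island summaries of SICER on mm9, per the submitters' processing notes. The window of 200 bases and the gap of 600 bases were read from the labels of the lists. The SICER version, the aligner, read filters and treatment of duplicate reads were not given in the sources used here. Each list was called on 1 ChIP library, and which input served as its control was not given. Islands of the same coordinates in 2 lists had the same control count in only 0.595 to 3.36% of cases, so the lists did not share a control count table. The labels of the lists name F3 tags of pairs for wild type and paired F3 and F5 tags with barcode for BD1del, so genotype and read set differ together.

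Each island carried 5 deposited values. The ChIP and control counts were whole numbers of reads per island as deposited by the authors, without normalization. The deposited p-value and FDR compared the ChIP count with the control count scaled by library size, and the largest deposited FDR was just under 0.01 in every list (0.00997 to 0.01000). The deposited fold is the ratio of ChIP to scaled control reads. From the counts and the fold, a ratio of ChIP to control library size was computed per list, 0.559 and 0.264 in wild-type spermatocytes and round spermatids and 0.177 and 0.184 in BD1del; it was the same for every island of a list. A Poisson upper tail with this ratio gave the deposited p-value, within 0.001 on the log10 scale, in 100% of the islands with a p above 1e-300, where islands without control reads were given 0.25 reads. Library sizes themselves were not recovered, so depth is given as reads in islands and as the ratio. The fold and p are the authors' and were used to describe, rank or filter islands within a list. Folds of different lists were also set side by side and, for overlapping islands, correlated by rank. The fold is already scaled by library size, but depth differed between lists and affects which folds can be called. Fold levels of different lists are therefore not directly comparable.

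Coordinates are 1-based on mm9, and chromosomes 1 to 19, X and Y were used. A list's islands were counted as overlapped when they shared at least 1 base with an island of the other list. Shares have exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only, since reads and neighbouring islands are not independent. Each share was set beside 100 random placements of the islands within the span of their chromosome, seeded, and beside 100 random moves of 10 to 500 kb in either direction. The moves, which keep regional density, were added after the data were examined; where alternatives were compared, 20 placements of each kind were drawn. Overlap counting was checked on simulated lists with known shares: for the stage overlap in wild type (36615 islands simulated), true shares of 20% and 60% were returned as 20.0% and 60.0%, and an unrelated list gave 13.5% against 13.6% by random placement. These simulated lists were built with the same placement and overlap rules that were being checked, so the agreement was largely fixed in advance. The span of a chromosome ran from the first to the last island of any list.

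The comparisons, the overlap rule, the alternatives and the rule for named regions were fixed before the data were examined. The rule named, in each list, the 3 islands of highest fold with at least 10 control reads and the 3 longest, and, in each comparison and direction, the 5 islands of highest fold with at least 10 control reads that share no base with the other list; the report gives the leading ones. Islands with the most ChIP reads were added after the data were examined, as were bins of 1 Mb covered to at least 20%, the limits of the blocks on chromosomes 1, 14 and X, and the division of lists into 5 parts by fold. Alternatives were an FDR of at most 1e-10, a fold of at least 2, equal lists of 10000 islands by p, at least 10 control reads, removal of the 1% of islands with most control reads per kb, merging within 1000 bases, overlap of at least 50% of the shorter or of both islands, covered bases in place of islands, and autosomes alone. With 1 library per group no test between groups was run.

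Promoter occupancy and the gene lists fixed beforehand were not analysed here, because the gene table at hand is of GRCm38 and the islands are on mm9, so no island was assigned to a gene. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.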

Results

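Binding of Brdt to chromatin was profiled by ChIP-seq in mouse male germ cells at 2 stages, meiotic spermatocytes and post-meiotic round spermatids, from adult wild-type mice and from mice that lack the first bromodomain of Brdt (BD1del). Brdt is a testis-specific member of the BET family whose bromodomains bind acetylated histones. The 8 samples were 4 anti-Brdt ChIP libraries and 4 input libraries, 1 of each for every combination of stage and genotype. Binding was described by 4 deposited lists of islands, 1 per ChIP library, in which reads clustered above a control library on mm9. With 1 library per group there was no replicate error, so every comparison below sets these libraries side by side and none has a test between groups. Single islands named for a high fold had at least 10 control reads. Intervals are exact (Clopper-Pearson) 95% binomial intervals and cover counting error only.

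With all islands, the 4 lists differed in number and form more than in the amount of genome they covered. Wild-type spermatocytes had 36615 islands with a median length of 2200 bases, and wild-type round spermatids had 74968 with a median of 1400. BD1del spermatocytes had 112671 islands with a median of 1200 bases, and BD1del round spermatids had 201828 with a median of 400. In the same order the islands covered 108 Mb, 130 Mb, 165 Mb and 152 Mb. Stricter lists differed more in covered genome: 33.3, 33.7, 97.8 and 106.3 Mb with an FDR of at most 1e-10. With a fold of at least 2 the values were 15.9, 75.8, 144.0 and 142.9 Mb. Islands made of a single 200-base window were 3.83% of the list in wild-type spermatocytes and 38.7% in BD1del round spermatids.

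Islands of the same 4 lists held 6476047, 4506707, 6391762 and 7310429 ChIP reads and 7147741, 7407692, 10905618 and 8482499 control reads. The control library was 1.79 times as deep as the ChIP library in wild-type spermatocytes, 3.79 times in wild-type round spermatids, 5.64 times in BD1del spermatocytes and 5.45 times in BD1del round spermatids. The median deposited fold of the islands over control was 1.67, 2.72, 3.79 and 7.05 in the same order. The labels of the lists also named different read sets, F3 tags of pairs for both wild-type lists and paired F3 and F5 tags for both BD1del lists, so genotype and read set could not be told apart. With islands of a deposited FDR of at most 1e-10 alone, the wild-type lists fell to 9202 and 23719 islands and the BD1del spermatocyte list to 74072. With a deposited fold of at least 2, the wild-type spermatocyte list fell to 10679.

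With all islands, the sex chromosomes were more densely covered than the autosomes as a whole in all 4 lists, and X most of all in wild-type spermatocytes. For X this rested on dense 1-Mb bins in 3 lists: without the bins covered to at least 20% in any list, the ratio of X to autosome coverage was 1.94 in wild-type spermatocytes, 0.867 in wild-type round spermatids, 0.891 in BD1del spermatocytes and 0.954 in BD1del round spermatids. Of the dense bins of each list in that order, 33 of 70, 11 of 45, 21 of 33 and 16 of 24 lay on X. Leaving them out therefore lowers the ratio by construction. Both sex chromosomes are transcriptionally silenced in pachytene spermatocytes, which is the background of this comparison between stages. In wild-type spermatocytes islands covered 14.4% of X and 3.46% of the autosomes, a ratio of 4.17. In wild-type round spermatids they covered 7.31% of X and 4.83% of the autosomes, a ratio of 1.51. The ratio was 1.48 in BD1del spermatocytes, where 9.13% of X was covered, and 1.52 in BD1del round spermatids, where 8.58% was covered. The covered share of Y, of which mm9 holds only a short part, was 47.0%, 35.8%, 37.2% and 29.2% in the order given above. Counted as islands, X held 18.5% (18.1 to 18.9%) of the wild-type spermatocyte list, 8.87% (8.67 to 9.08%) of the wild-type round spermatid list, 6.19% (6.05 to 6.33%) of the BD1del spermatocyte list and 5.30% (5.20 to 5.40%) of the BD1del round spermatid list. X makes up 6.34% of the span of the chromosomes. When each list was held to its 10000 islands of lowest p, the ratio of X to autosome coverage was 6.80 and 2.60 in the wild-type lists. It was 5.79 and 5.61 in the BD1del lists, so wild-type and BD1del spermatocytes then differed less in this ratio. This selection changed stringency along with list length. X itself was then covered to 6.70%, 1.23%, 2.85% and 1.80% in the order given above. With an FDR of at most 1e-10 the ratio was 7.002, 1.72, 1.77 and 1.57, a wider contrast between the genotypes in spermatocytes. X itself was then covered alike in wild-type and BD1del spermatocytes, at 6.33% and 6.35%. This contrast therefore came from the autosomes, at 0.904% against 3.58%. With a fold of at least 2 the ratio was 1.92 and 0.943 in the wild-type lists and 1.26 in each BD1del list, but X itself was then least covered in wild-type spermatocytes, at 1.11% against 2.77%, 6.86% and 6.85%. The autosomes were least covered there too, at 0.581% against 2.94%, 5.46% and 5.43%, so this low coverage was not particular to X.

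**Figure D1:**
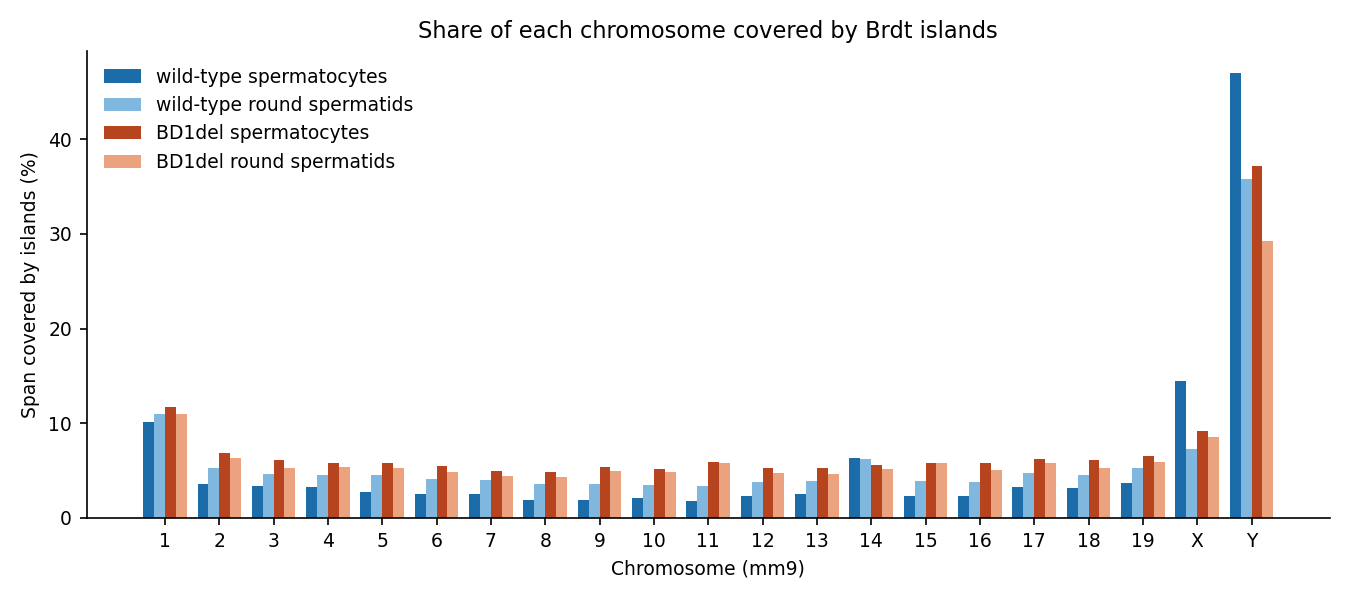
Percent of each chromosome's span (vertical axis, from the first to the last island of any list) covered by Brdt islands on the 19 autosomes, X and Y (horizontal axis), with a bar for each of the 4 lists. Chromosome 1 was the most covered autosome in every list, at 10.1 to 11.8%, and X stood at 14.4% in wild-type spermatocytes against 7.31 to 9.13% in the other lists.

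The additional X coverage of wild-type spermatocytes lay mainly in a few megabase-scale blocks. Between 24 and 33 Mb, islands covered 66.0% of X in wild-type spermatocytes, 11.0% in wild-type round spermatids, 4.25% in BD1del spermatocytes and 5.04% in BD1del round spermatids. Between 3 and 5 Mb the same values were 63.6%, 11.3%, 5.47% and 5.35%, and between 51 and 53 Mb they were 27.5%, 4.50%, 3.17% and 2.67%. A block from 120 to 123 Mb was covered to 56.2% in wild-type spermatocytes and to 29.3% in BD1del spermatocytes, against 13.8% and 10.3% in the wild-type and BD1del round spermatids. Without these blocks and another that starts at 144 Mb, 19 bins of 1 Mb in all, X was covered to 8.91%, 6.73%, 8.96% and 8.68% in the 4 lists. The autosomes were covered to 3.46%, 4.83%, 6.18% and 5.66%. These bins were chosen for their coverage in the wild-type spermatocyte list alone, so leaving them out lowers X in that list by construction. The distal end of X, which carries the pseudoautosomal region, was similarly dense in every list: from 150 Mb on, islands covered 23.3%, 20.9%, 23.8% and 22.8%. Blocks were taken as runs of 1-Mb bins covered to at least 20%, a limit chosen after the profiles were seen. Folds there were low: summed over wild-type spermatocyte islands from 24 to 33 Mb, ChIP reads were 1.45 times scaled control reads. Islands of fold under 2 were few in BD1del, where 105394 of 112671 spermatocyte and 198412 of 201828 round spermatid islands had at least 2. A limit of calling therefore cannot be told apart from lower binding in the BD1del lists.

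The longest dense blocks on autosomes, on chromosomes 1 and 14, were found at both stages in wild type. On chromosome 1 from 3 to 24 Mb, next to the centromere, islands covered 47.6% in wild-type spermatocytes and 37.7% in wild-type round spermatids, but 15.0% and 14.2% in the BD1del lists. The block ended sharply in wild-type spermatocytes, from 54.8% of the bin that starts at 23 Mb to 9.0% of the next. The rest of chromosome 1 was covered to 5.53% and 7.68% in wild type and to 11.3% and 10.5% in BD1del. On chromosome 14 from 3 to 9 Mb the covered share was 67.3% and 41.7% in the wild-type lists and 5.77% and 12.96% in the BD1del lists. The rest of chromosome 14 was covered to 3.14% and 4.41% in wild type and to 5.48% and 4.67% in BD1del. BD1del round spermatids were thus also denser in the block. Control reads were denser in this block too. Its islands of at least 1000 bases had 1.59 times as many control reads per kb as those on the rest of chromosome 14 in wild-type spermatocytes. The ratio was 2.02 in wild-type round spermatids, and 1.44 and 1.19 in the BD1del lists. On chromosome 1 the same ratio was 0.892, 1.24, 1.09 and 1.10.

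**Figure D2:**
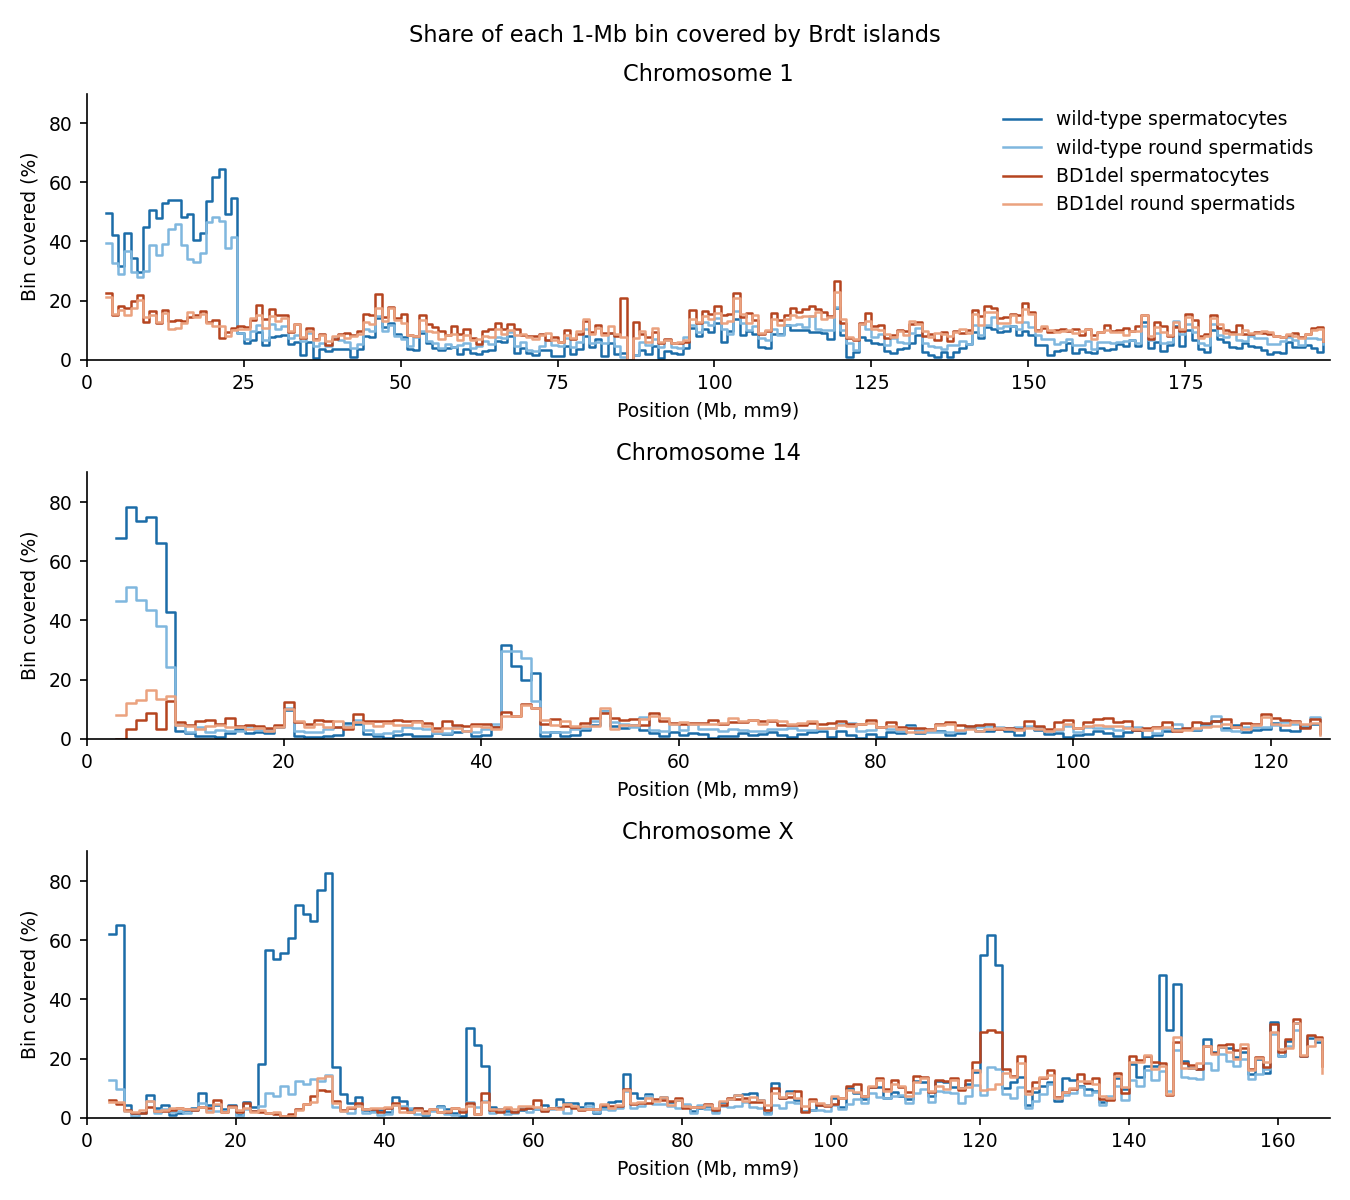
Percent of each 1-Mb bin covered by Brdt islands (vertical axis) along chromosomes 1, 14 and X (horizontal axis, Mb on mm9), with a line for each of the 4 lists. The wild-type lists rise at 3 to 24 Mb of chromosome 1 and 3 to 9 Mb of chromosome 14, wild-type spermatocytes alone reach 66.0% at 24 to 33 Mb of X, and the 4 lists run close together from 150 Mb of X on.

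Brdt islands of wild-type spermatocytes met islands of wild-type round spermatids far more often than moved islands did. Of the spermatocyte islands, 58.9% (58.4 to 59.4%) shared at least 1 base with a round spermatid island, against 14.2% for islands placed at random on their chromosome and 19.04% for islands moved at random by 10 to 500 kb. In the other direction 30.3% (30.0 to 30.7%) of the round spermatid islands were overlapped, against 7.43% and 10.1%. The longest island of either list was a single stretch on chromosome 6, 114439601 to 114588400, which spanned 148.8 kb in spermatocytes and 148.4 kb in round spermatids, with deposited folds of 2.13 and 1.68. It held 13163 control reads in spermatocytes and 18812 in round spermatids. Islands of the BD1del lists covered 5.78% of that stretch in spermatocytes and 12.6% in round spermatids. Another long spermatocyte island, chromosome 8, 126061401 to 126149200, was covered to 99.1% by round spermatid islands and to 3.87% in each BD1del list. Islands there held 6100 control reads in wild-type spermatocytes and 7760 in wild-type round spermatids. By contrast, an island of 90.8 kb on X, 120274001 to 120364800, held no round spermatid island of wild type, and BD1del spermatocyte islands covered 40.3% of it. Its fold was 1.37, from 14721 ChIP and 19167 control reads. All these stretches were denser in control reads than the median autosomal island of at least 1000 bases. That median was 40.0 per kb in wild-type spermatocytes and 33.1 in wild-type round spermatids. Whether reads piled up there was not tested.

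Islands of high fold that met no island of the other stage spanned 200 to 2600 bases among the leading 5 of each stage in wild type. The leading wild-type spermatocyte island of this kind was chromosome 10, 3831001 to 3833000, with a fold of 21.5, which met islands of both BD1del lists. The leading round spermatid island was chromosome 8, 23163001 to 23163800, with a fold of 30.3, and none of the 5 leading islands of that kind met an island of any other list. Across the 23470 pairs of overlapping islands the folds of the stages had a Spearman correlation of 0.547, which is across islands, and islands are not independent replicates. With islands of FDR at most 1e-10 the share of spermatocyte islands overlapped was 31.9%, and with the 10000 islands of lowest p per list it was 18.6%, against 6.82% and 3.66% after random moves.

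The stages overlapped less in BD1del cells, although both lists were longer. Of the BD1del spermatocyte islands 24.24% (23.99 to 24.49%) met a round spermatid island, against 15.5% at random on the chromosome and 16.3% after random moves. In the other direction 13.9% (13.8 to 14.1%) of the round spermatid islands were met, against 8.93% and 9.36%. The overlap was thus 1.49 times that of moved islands, where it was 3.09 times in wild type. Of the BD1del spermatocyte islands, 60.9% of those on X were overlapped and 21.6% of those on autosomes. Moved islands gave 15.4% on autosomes alone. No such value was computed for X alone, which was more densely covered, so chance may give part of this gap. With the 10000 islands of lowest p per list, the overlap was 13.04% in BD1del and 18.6% in wild type, which was 10.4 and 14.9 points above moved islands, or 5.03 and 5.08 times their share. With a fold of at least 2, the share of round spermatid islands met was 7.98% in wild type and 12.1% in BD1del, against 1.22% and 8.18% after random moves. The contrast itself had no test.

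Among BD1del islands that met no BD1del island of the other stage, the spermatocyte island of highest fold was chromosome 17, 7138001 to 7140800, at 39.0, and the round spermatid island of highest fold was chromosome 2, 171688601 to 171689200, at 41.9. Both met islands of both wild-type lists. The longest BD1del spermatocyte islands had folds close to 1. An island of 89.0 kb on chromosome 8, 19917201 to 20006200, had a fold of 1.16 and was covered to 56.4% in BD1del round spermatids but to 0% in both wild-type lists. Another of 80.8 kb on chromosome 11, 3019201 to 3100000, had a fold of 1.06 and no island of any other list within it.

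In spermatocytes the genotypes shared a minority of the islands of either list. Of the wild-type islands 35.0% (34.5 to 35.5%) shared a base with a BD1del island, against 18.3% at random on the chromosome and 19.8% after random moves. Of the BD1del islands 11.9% (11.8 to 12.1%) met a wild-type island, against 6.41% and 6.82%. On X the shares were 52.8% and 53.4%, and on autosomes 30.4% and 8.96%. Moved islands gave 17.9% and 5.33% on autosomes alone, and no such value was computed for X. The leading island of wild-type spermatocytes that met no BD1del spermatocyte island was chromosome 15, 99222801 to 99224600, at a fold of 17.6, which met no island of any other list. The leading BD1del island that met no wild-type spermatocyte island was chromosome 6, 132413401 to 132414000, 600 bases long, at a fold of 62.5, and it met islands of both round spermatid lists. Among BD1del spermatocyte islands with at least 10 control reads, the one of highest fold, chromosome 17, 4626001 to 4626800, at 91.4, met an island of every other list. The genotypes also differed in read set and in control depth, and with 10000 islands per list the share of wild-type islands overlapped was 12.97%, against 4.10% after random moves.

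In round spermatids the genotypes likewise shared a minority of the islands. Of the wild-type islands 29.1% (28.8 to 29.4%) were met by a BD1del island, against 17.4% at random on the chromosome and 18.3% after random moves. Of the BD1del islands 11.2% (11.1 to 11.3%) met a wild-type island, against 6.80% and 7.13%. On X the shares were 54.3% and 34.0%, against 26.4% and 9.79% on autosomes. Moved islands gave 17.5% and 6.51% on autosomes alone, and no such value was computed for X. The wild-type island of highest fold that met no BD1del round spermatid island was chromosome 14, 15691801 to 15692400, at 43.6. On the BD1del side it was chromosome 7, 150720001 to 150720400, at 56.9, with a neighbour on the same chromosome, 150715201 to 150715600, at 41.6 among the first 5. In all 4 comparisons the rule for islands that the other list of the comparison does not meet named 40 islands, of which 34 were distinct. Of the distinct islands, 27 spanned at most 1000 bases and 13 met no island of any other list. With 10000 islands per list the share of wild-type islands overlapped was 8.09%, against 1.99% after random moves.

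**Figure D3:**
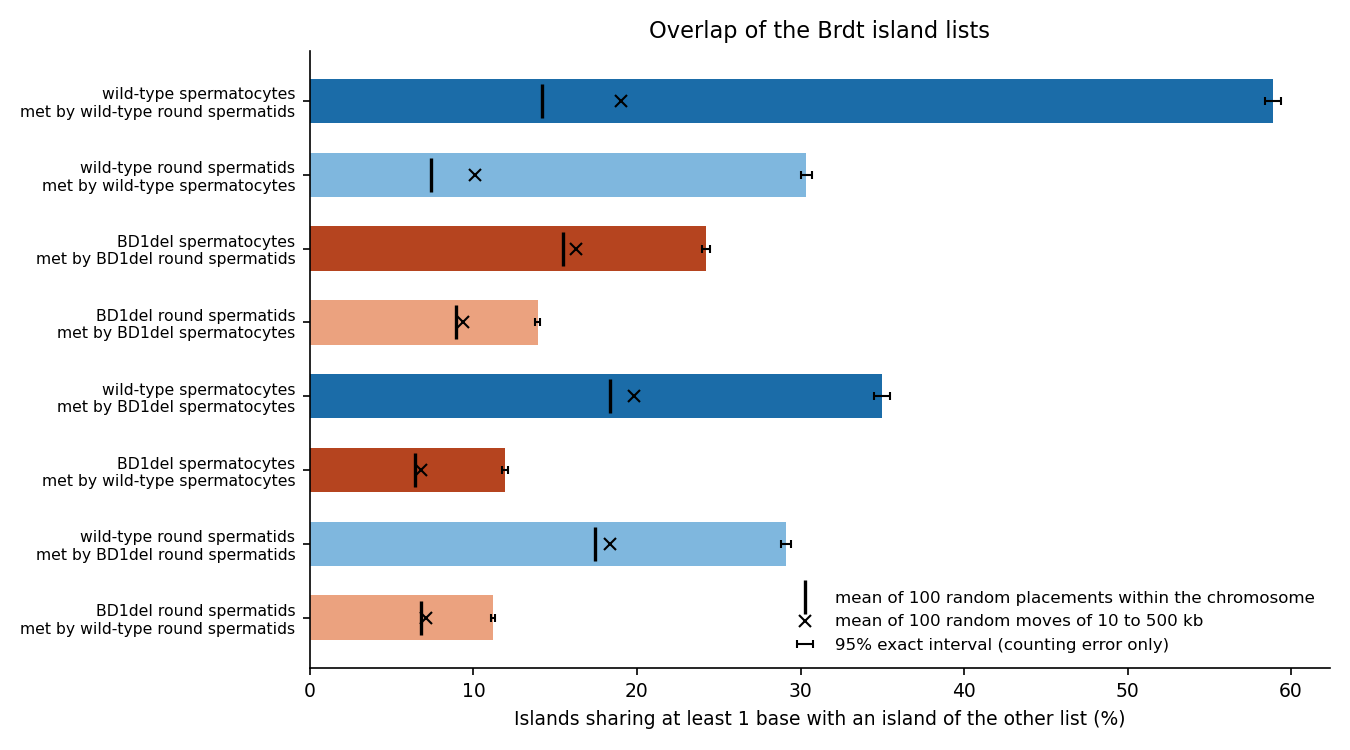
Percent of the islands of a list (horizontal axis) that share at least 1 base with an island of the list named beside them, for the 4 comparisons in both directions, with exact 95% intervals for counting error. Vertical ticks mark 100 random placements within the chromosome and crosses 100 random moves of 10 to 500 kb; every bar lies beyond its marks, by most in wild type between stages (58.9% against 19.04%).

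A common set of islands was found in all 4 lists, and most of it lay on X and chromosome 1. Of the wild-type spermatocyte islands, 7288 (19.9%) met an island in each of the other 3 lists, as did 7233 (9.65%) of the wild-type round spermatid, 7054 (6.26%) of the BD1del spermatocyte and 7111 (3.52%) of the BD1del round spermatid islands. X held 33.0 to 33.9% of this set and chromosome 1 held 28.2 to 29.2%, depending on the list counted. No random placement was run for meeting all of the other 3 lists. Both chromosomes were more covered than the autosomes as a whole, so the part due to chance was not measured. From 150 Mb on, X held 56.4 to 58.0% of the part on X. At the other extreme 24.2% of the wild-type spermatocyte islands met no island of any other list, and 48.9%, 67.4% and 77.7% of the other lists in the order used above. The islands with the most ChIP reads were examined after their values were seen, and those named here met an island in each of the other lists. On chromosome 9, 2999801 to 3038800, islands held 452237 ChIP and 359691 control reads in wild-type spermatocytes, or 6.98% of all ChIP reads in islands there, and 4.13 to 7.21% in the other lists. Control reads in these 39.0 kb were far denser than the 40.0 per kb of the median autosomal island of at least 1000 bases. Piled-up reads therefore cannot be told apart from binding there. On X, 166407601 to 166447000, the wild-type spermatocyte island held 45852 ChIP and 24648 control reads at a fold of 3.33. Islands of the other lists covered 94.9%, 79.7% and 70.1% of it. Control reads in these 39.4 kb were also far denser than that median, so piled-up reads cannot be told apart from binding there either.

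Islands of high fold were met by other lists less often than islands of low fold, a relation examined after the overlaps were seen. Each list was divided by fold into 5 groups of equal number. In wild-type round spermatids, spermatocyte islands met 60.7% of the lowest group and 8.06% of the highest group, against 22.0% and 3.89% after random moves. In wild-type spermatocytes round spermatid islands met 63.6% of the lowest and 45.1% of the highest group, against 30.9% and 8.66% after random moves, so relative to moved islands the overlap was higher in the highest group, 5.22 times against 2.06 times. In BD1del round spermatids the highest group was met by BD1del spermatocyte islands in 5.98%, against 6.32% after random moves, and by wild-type round spermatid islands in 3.74%, against 4.62%. Its islands had a median fold of 21.8. Among islands with at least 100 ChIP reads the relation was not uniform: the highest group minus the lowest ranged from -16.4 to 8.64 percentage points over the 8 directions.

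**Figure D4:**
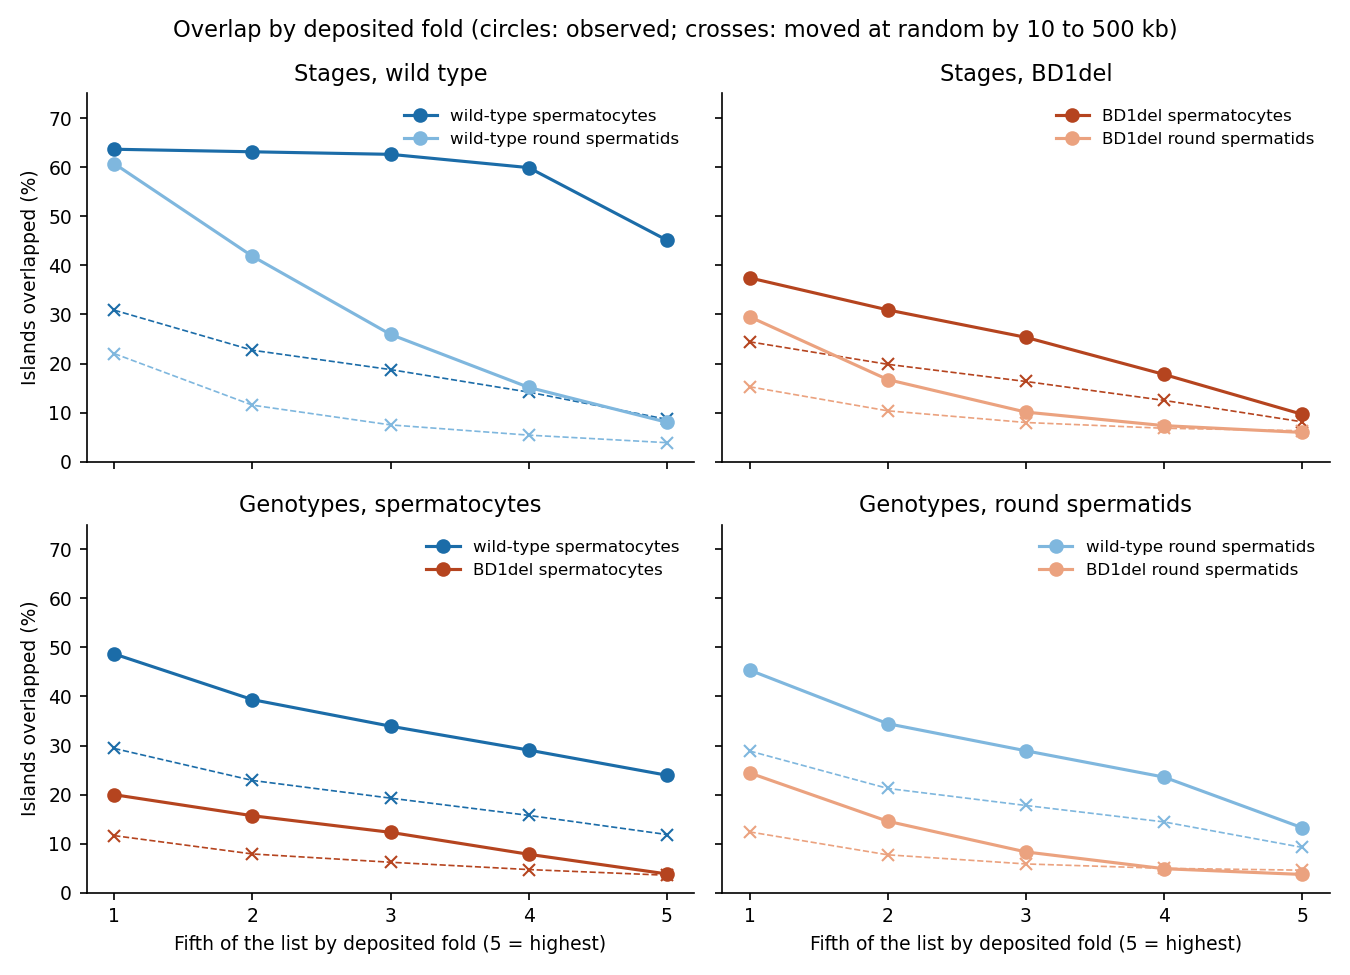
Percent of islands overlapped by the other list of each comparison (vertical axis) in 5 equal groups of each list by deposited fold (horizontal axis, 5 is the highest), with circles for the observed share and crosses for islands moved at random by 10 to 500 kb. In wild-type round spermatids the share falls from 60.7% to 8.06%, and in the highest group of BD1del round spermatids observed and moved islands lie at 5.98% and 6.32% for the stages.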

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

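All tests of explanations in this part were chosen after the results were seen. The results below stood out because, with all islands, the lists of one genotype or stage differed in the opposite direction from those of the other. With 1 library per group none of these differences was tested.

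From spermatocytes to round spermatids the covered genome was 21.3 Mb larger in wild type and changed by -13.7 Mb in BD1del. The BD1del direction turned with an FDR of at most 1e-10, from 97.8 to 106.3 Mb, where wild type went from 33.3 to 33.7 Mb. With a fold of at least 2 BD1del went from 144.0 to 142.9 Mb and wild type from 15.9 to 75.8 Mb. From wild type to BD1del the covered share of X changed by -5.28 percentage points in spermatocytes and by 1.27 points in round spermatids. The fall in spermatocytes was not seen with an FDR of at most 1e-10, where X went from 6.33% to 6.35%, nor with a fold of at least 2, from 1.11% to 6.86%. Round spermatids rose in both settings, from 2.11% to 6.20% and from 2.77% to 6.85%. The ratio of X to autosome coverage changed from spermatocytes to round spermatids by -2.66 in wild type and by 0.0381 in BD1del. From wild type to BD1del it changed by -2.69 in spermatocytes and by 0.00345 in round spermatids. The small rises of 0.0381 and 0.00345 depended on the setting. With an FDR of at most 1e-10 both were falls: the ratio was 1.77 in BD1del spermatocytes, 1.72 in wild-type round spermatids and 1.57 in BD1del round spermatids. With a fold of at least 2 both stayed rises. The larger X contrasts all involved the wild-type spermatocyte list, whose ratio was 4.17 against 1.48 to 1.52 in the other lists, although in lists of 10000 islands the ratio was 5.79 and 5.61 in BD1del and 6.80 in wild-type spermatocytes.

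This X coverage of wild-type spermatocytes was weighed against 3 explanations. Weak islands called in that list alone stay open: with islands of fold at least 2 the ratio of X to autosome coverage was 2.03 times that of wild-type round spermatids, but X was then covered to 1.11%, against 2.77%, 6.86% and 6.85% in the other lists. The autosomes were then also least covered in that list, at 0.581% against 2.94%, 5.46% and 5.43%, so the X value alone does not decide. Reads piled up from sequence with more copies in the genome than in the assembly may still contribute, but the control reads do not decide. Control reads per kb in the dense X blocks were 0.829 times those of other X islands. They were 2.14 times what a chromosome present once would give from the autosomal islands. Other X islands were denser still, at 51.7 per kb against 42.9, so this excess was not particular to the blocks. Control reads were also counted only in called islands. The 0.829 rests on a median over all these blocks, and control reads were spread unevenly between them. Islands from 120 to 123 Mb held 299144 control reads, and those of the larger block from 24 to 33 Mb held 326499. Higher binding on X in spermatocytes of either genotype stays open, because the direction in BD1del depended on the setting. With all islands the BD1del ratio in spermatocytes was 0.975 times that in round spermatids. It was 1.77 against 1.57 with an FDR of at most 1e-10, and 5.79 against 5.61 in lists of equal length. With a fold of at least 2 it was 1.255 against 1.261, and without dense bins 0.891 against 0.954. BD1del islands covered 29.3% of the block from 120 to 123 Mb in spermatocytes and 10.3% in round spermatids, but 4.25% and 5.04% from 24 to 33 Mb. With no read set common to the genotypes, a difference between them cannot be told apart from the way those lists were made. Binding on X that needs the first bromodomain stays open and was not tested.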

How the results depend on the processing

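All alternatives except the removal of dense bins were fixed before the data were examined. No paired analysis was possible because each group had 1 library, so the groups share only 1 number; for the same reason no library could be left out and no split of samples made. Thinning to equal depth was not run, as absolute library sizes could not be recovered, and nothing on promoter occupancy was run, including both other windows. Values below follow the order wild-type spermatocytes, wild-type round spermatids, BD1del spermatocytes and BD1del round spermatids for X, and stages in wild type, stages in BD1del, spermatocytes between genotypes and round spermatids between genotypes for overlap. Under every alternative run, the share of spermatocyte islands met by round spermatid islands stayed higher in wild type than in BD1del. The share of round spermatid islands met did not with a fold of at least 2, where it was 7.98% in wild type and 12.1% in BD1del, against 1.22% and 8.18% for islands moved nearby. X held its largest share of islands in wild-type spermatocytes throughout. Overlaps below are shares of the spermatocyte islands between stages and of the wild-type islands between genotypes, and merging islands within 1000 bases moved none of these beyond its interval.

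With an FDR of at most 1e-10, island numbers were 9202, 23719 and 74072 in the first 3 lists, overlaps 31.9%, 17.8%, 30.6% and 21.5%, the X share 17.4% and 7.48% in the wild-type lists and 5.03% in BD1del round spermatids, and X over autosome coverage 7.002 in wild-type spermatocytes. With a fold of at least 2, wild-type spermatocytes kept 10679 islands, overlaps were 41.8%, 22.2%, 24.3% and 23.8%, X shares 11.5%, 6.87%, 5.59% and 4.91%, and X over autosome coverage 1.92 and 0.943 in the wild-type lists. With 10000 islands per list, overlaps were 18.6%, 13.04%, 12.97% and 8.09%, X shares 17.5%, 9.26%, 13.1% and 11.5%, and X over autosome coverage 6.80, 2.60, 5.79 and 5.61. Without the 1% of islands densest in control reads, overlaps were 57.4%, 22.9%, 32.7% and 27.3% and X shares 18.1%, 8.39%, 5.60% and 4.799%. With at least 10 control reads, overlaps were 22.8% between stages in BD1del and 28.7% between genotypes in round spermatids, and X shares 9.23% and 5.44% in the wild-type and BD1del round spermatids. Overlaps were 58.1%, 21.6%, 30.4% and 26.4% on autosomes alone, 55.6%, 21.9%, 31.9% and 26.5% when at least 50% of the shorter island had to be shared, 34.4%, 9.76%, 17.5% and 11.9% when at least 50% of both had to be, and 40.1%, 18.1%, 23.3% and 19.03% in covered bases. Without dense bins, overlaps were 56.0%, 22.2%, 31.5% and 26.6%, X shares 11.2%, 5.31%, 4.03% and 3.76%, and X over autosome coverage 1.94, 0.867, 0.891 and 0.954. Shorter lists leave fewer islands to meet, which by construction lowers an overlap; the cause of the other changes was not tested.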

Other observations

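The tests of few ChIP reads and of list length were set before their results were seen; the other tests in this part were chosen after the results were seen.

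Islands met by all other lists made up a larger part of the islands on X than of those on autosomes. Of the islands on X, 35.5% in wild-type spermatocytes, 36.0% in wild-type round spermatids, 34.2% in BD1del spermatocytes and 22.6% in BD1del round spermatids met an island in all 3 other lists, against 15.8%, 6.78%, 4.21% and 2.33% of those on autosomes. These shared islands were long and low, with a median length of 1800 to 2800 bases and a median fold of 1.54 to 3.24. Islands met by no other list had a median length of 400 to 2000 bases and a median fold of 1.79 to 7.96. Shared islands also had more control reads, with a median of 60.0 to 74.5 per kb against 29.1 to 49.2 per kb in the islands met by no other list. No random placement was run for meeting all 3 other lists, so the part due to chance was not measured.

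A small island of BD1del spermatocytes on chromosome 17, 4626001 to 4626800, had the highest fold among islands with at least 10 control reads in any list, 91.4, from 1426 ChIP and 88 control reads, and met an island in all 3 other lists. In wild-type spermatocytes the highest fold by the same rule was 26.5, on chromosome 1, 120284801 to 120287000. The control was 5.64 times as deep as the ChIP library in BD1del spermatocytes and 1.79 times in wild-type spermatocytes. The fold is already scaled by library size, but depth affects which folds can be called. The folds of these lists are therefore not directly comparable. Near the centromeric end of chromosome 17, an island at 3004801 to 3039400 in BD1del round spermatids was covered to 98.3% in wild-type round spermatids and to 98.8% in BD1del spermatocytes but to 0% in wild-type spermatocytes.

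Islands of high fold were overlapped less often than islands of low fold, and 3 explanations were tested. Chance, in that shorter islands and islands in regions of few islands meet another list less often, stays open: the overlap in excess of islands moved nearby was more than 5 percentage points lower in the highest than in the lowest of 5 groups by fold in 7 of the 8 directions, from -34.5 to 3.71 points, but the ratio to moved islands was lower in only 6 directions and higher in 2. Few ChIP reads in the islands of high fold may account for part of it, since among islands with at least 100 ChIP reads the highest group was at least 10 points lower in only 1 of the 8 directions, but it was not higher throughout either. Binding particular to the cell stage would make the highest group meet the same stage of the other genotype more often; this held in 3 of the 4 lists, by as little as 1.0739 against 1.0735 times the moved islands in BD1del spermatocytes, and in BD1del round spermatids both values, 0.810 and 0.607, lay below those of moved islands, so it does not decide.

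The lower overlap of the stages in BD1del than in wild type was also weighed. Bins dense in islands are argued against, because without them the overlap in excess of moved islands was larger in wild type by 36.9 percentage points, against 31.8 with them. Lists of different lengths may contribute: with 10000 islands per list the difference was 4.48 points, from 14.9 in wild type and 10.4 in BD1del, and the overlap was 5.08 and 5.03 times that of moved islands. Keeping the islands of lowest p changed stringency along with length, so these cannot be told apart. The read sets were named differently for the genotypes, with 0 read sets in common, so a difference in the reads used cannot be told apart from one between the genotypes. An effect of the deleted bromodomain on where Brdt binds at each stage stays open and was not tested.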
